A study of Aspergillus nidulans with 32 samples.

How the data were processed

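Polyadenylated RNA of mycelium was sequenced in 32 libraries. Per the labels' protocols, cultures grew at 37 °C with shaking in minimal medium with glucose and nitrate, and the salt solution was that medium without its carbon and nitrogen sources. Libraries were made with the TruSeq RNA kit v2 and read as 50 nt single ends on a HiSeq instrument, per the labels. The reads were mapped by the authors to the genome of strain FGSC A4. The submitters' processing notes name Trimmomatic 0.36, BWA, HTSeq, limma and edgeR without giving the step each served, and the gene annotation and any filter are not given in the sources used here. The kit keeps no strand, so reads of overlapping or antisense genes cannot be told apart. The labels name the strains WT FGSC#4 and alcA(p)-sGFP-aflR (RKIS42.17), in the latter of which, by its name, the alcA promoter drives aflR, without stating which strain gave which sample, so levels of aflR hold for an unstated strain.

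The authors deposited raw counts per gene, as whole numbers in 1 column per library, and these counts were the values used here. Columns of log2 FPKM deposited by the authors, 1 per group for 8 groups, and a column of log2 exon length in kb were checked against the counts and not used further. Per gene, the deposited log2 FPKM of the grown group differed from the value computed from counts and length by a median of 0.21 with an SD of 0.12 over 5461 genes, and the median over the groups ran from -0.31 to 0.34.

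The table held 10681 genes, of which 97 had no count. Counts of the 2 technical libraries of a culture were summed, because the labels call the letters A and B biological and the numbers technical replicates, so the culture was the replicate. The 2 technical libraries of a culture differed by a chi-square per degree of freedom of 2.12 to 2.29, and cultures of a group by 44.2 to 272. With R 4.3.3, edgeR 4.0.16 kept 10022 genes by filterByExpr with the groups, a minimum count of 10 and a minimum total of 15. The 659 genes left out held 0.00149% of the counts. Sums were scaled by TMM, and 1 model with a mean per group was fitted to all 16 cultures with the quasi-likelihood functions of edgeR (8 residual degrees of freedom, prior degrees of freedom 4.07, common biological coefficient of variation 0.160). The tests were 2-sided, p was adjusted by Benjamini-Hochberg over the tested genes of a comparison, and the threshold was 0.0500. For a gene with a group at 0 counts, the fold change was bounded by setting that group to 3 counts over the group. Such bounds cover counting error only. Principal components were taken of log2 CPM with a prior count of 2.

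The 12 comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, the genes with the 5 largest rises and the 5 largest falls among called genes with a mean of at least 10 CPM in the higher group and with both cultures of a group on the same side. It also named up to 4 members per list, those with the 2 largest and the 2 smallest log2 changes, and aflR, stcA and stcU in every comparison. Genes named by the rule may be left out of the text. Gene sets for renewed starvation needed the same sign and a call in the response of pre-starved cultures, in the comparison of pre-starved with naive cultures, and in the difference of the responses.

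The 28 lists were 12 secondary metabolite clusters (sterigmatocystin, penicillin, monodictyphenone, asperthecin, emericellamide, orsellinic acid, terrequinone, aspyridone, asperfuranone, cichorine, austinol and the benzaldehyde derivative cluster) and 16 functional groups. The functional groups were nitrate assimilation, nitrogen regulation and alternative nitrogen use, ammonium assimilation, glycolysis, gluconeogenesis and acetate use, alcohol use and carbon repression, autolysis and extracellular hydrolases, and autophagy. The others were trehalose and glycerol, oxidative stress defence, heat shock proteins, histones, chromatin regulators, secondary metabolism regulators, asexual development with conidial genes, and sexual development regulators. Of 225 members 218 were in the table and 199 were tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.0100 and again with the correlation estimated, and with fry. The 3 lists planned from gene descriptions (ribosomal proteins, ribosome biogenesis and the proteasome) were not used here. Gene symbols of list members are background knowledge: the reference annotation of assembly ASM1142v1, used for names and gene order alone, gave a symbol for 67 of them, the same one for 48. Members with a different symbol there were kept. The plan was to drop any whose symbol contradicted the expected one, and no member was dropped. That annotation held 9970 of the gene identifiers. Genomic positions are not given, since the deposited counts rest on another annotation release.

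The procedure was tested on simulated data of 9871 genes in the same design. Of 100 genes changed 2-fold between pre-starved and naive salt cultures 78% were called, of as many changed 4-fold 100%, and 4.81% of the calls were false. For the difference of the salt responses the shares were 48%, 96% and 4%. All simulated groups had the levels of naive salt cultures, and only the changed genes differed, as many up as down, in pre-starved salt cultures. The spread of a gene was the same in every group. These shares therefore do not cover changes of most genes between media, nor a spread that differs between groups.

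The alternatives were RLE size factors, library totals without TMM, no low-count filter, limma-voom on the sums, DESeq2 1.42.0 with its Wald test, all 32 libraries with duplicate correlation, either technical library alone, a block for the culture letter, only the groups of a comparison, a threshold that also asks for a 2-fold change, and leaving out each culture in turn. A pair of further comparisons, of used with salt medium within naive and within pre-starved cultures, was chosen after seeing the data.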

Results

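Polyadenylated RNA from mycelium of Aspergillus nidulans, a filamentous fungus grown in shaken liquid culture, was measured by RNA sequencing in 32 libraries. The libraries came from 16 cultures in 8 groups, with 2 cultures (A and B) per group and 2 technical libraries per culture. Grown cultures spent 24 h in minimal medium with glucose and nitrate. Starved cultures spent 20 h in that medium and then 4 h in a salt solution without a carbon or nitrogen source. Naive cultures went from growth straight into fresh medium for 2 h, and pre-starved cultures went into fresh medium for the same time after the starvation. Refed cultures of each kind were then moved for 1 h into the salt solution or into used medium, in which the fungus had already grown for 48 h. Starved and pre-starved cultures had thus grown for 20 h and all others for 24 h, and no group grew for 20 h without starvation. They also had a further change of medium compared with grown or naive counterparts. In those comparisons, effects of starvation, of shorter growth and of the further change cannot be told apart. The series title names transcriptional memory of secondary metabolite production, so the central question was whether an earlier starvation changed the response to a later one.

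Library totals ran from 19634577 to 33202687 counts, and the summed total of a culture from 39526910 to 66121549 counts. Expression is given in CPM, counts scaled to library size by trimmed means (TMM), as mean ± SD over the n = 2 cultures of a group, and changes as log2 fold changes with their standard error (SE). Of 10681 genes in the table, 10022 were tested. Every adjusted p of a gene comes from the quasi-likelihood test of edgeR with the Benjamini-Hochberg method over all tested genes, and a gene is called higher or lower when it lies under 0.05. For each gene named as called, the direction was the same in cultures A and B. On the first principal component of log2 CPM, which held 72.4% of the variance, grown and refed cultures lay apart from cultures in salt or used medium. On the second, with 10.8%, starved and pre-starved cultures lay apart from grown and naive cultures. Scaling by library totals alone shifted the median log2 change of all genes by -0.67 in the refeeding comparison and by 0.76 in the salt comparison of pre-starved cultures, the extremes over the 12 comparisons, so changes are to be read relative to the bulk of genes. Over 336 tests of 28 fixed gene lists, camera with its preset correlation called 47. With the correlation estimated from the cultures camera called 0 (17 at an unadjusted p under 0.05), and fry, which asks only whether the members of a list move one way, called 217. In the 12 comparisons, a list given without camera's adjusted p was not called by camera. Counts of list members are to be read against the share of all genes called. That share was 73.4% to 76.9% for the first starvation, refeeding and the moves into salt or used medium.

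**Figure D1:**
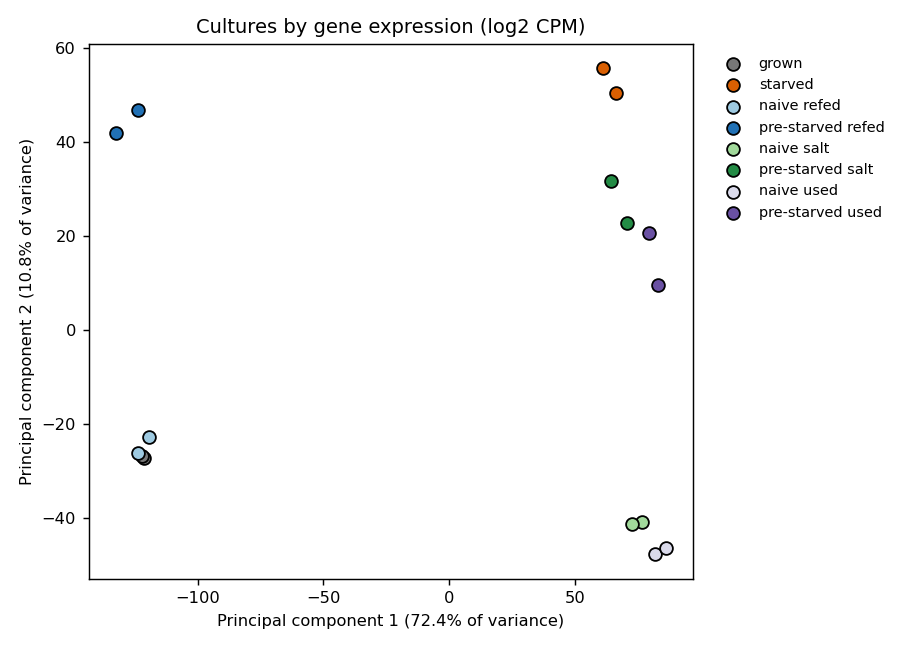
Each point is 1 culture, placed by the first (x axis) and second (y axis) principal component of log2 CPM over the tested genes, coloured by group. Grown and refed cultures sit on the left and cultures in salt or used medium on the right, and pre-starved cultures sit above naive cultures on both sides.

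The comparison of starved with grown cultures measured the response to the first starvation. Genes for the use of nitrate and sugar fell. The nitrate reductase gene niaD fell from 1473 ± 75.8 to 2.75 ± 0.633 CPM (log2 change -9.06, SE 0.24, adjusted p 6.61e-11). Of the 5 tested nitrate assimilation genes 4 were lower, and the pathway activator nirA was not called (log2 change -0.22, SE 0.12, adjusted p 0.112; log2 change 0.28 with library totals). All 11 tested genes of the glycolysis list were lower, from hxkA, hexokinase (log2 change -0.85, SE 0.12, adjusted p 3.05e-05), to pdcA, pyruvate decarboxylase (log2 change -6.86, SE 0.27, adjusted p 5.05e-10). The list counts pdcA as a member throughout, although its enzyme acts after glycolysis. The 3 ammonium assimilation genes fell too, gdhA, the glutamate dehydrogenase of that pathway, by most (log2 change -4.36, SE 0.14, adjusted p 1.26e-10). The 5 genes for autolysis and extracellular hydrolases rose, among them the metalloprotease gene pepJ (log2 change 11.36, SE 0.58, adjusted p 3.67e-09) and the alkaline protease gene prtA, from 53.2 ± 3.03 to 1554 ± 188 CPM (log2 change 4.87, SE 0.26, adjusted p 5.57e-09). Camera's adjusted p for these lists was 0.00426, 1.79e-04, 0.0238 and 0.0165 in the order named, and an adjusted p of 0.471 for each with the estimated correlation.

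Secondary metabolite clusters moved in both directions during the first starvation. The gene aflR, whose product activates the sterigmatocystin cluster, rose from 0.266 ± 0.0689 to 21.2 ± 2.77 CPM (log2 change 6.30, SE 0.42, adjusted p 3.47e-08). The labels do not say whether any sample came from the strain alcA(p)-sGFP-aflR, so its levels hold for an unstated strain. Of 17 tested genes of that cluster 10 were higher and 5 lower, the same numbers when adjusted over the list alone, and the lower ones included stcV (log2 change -5.53, SE 0.31, adjusted p 7.53e-09) and stcA, the polyketide synthase gene (log2 change -1.42, SE 0.26, adjusted p 3.50e-04). All 3 tested terrequinone genes rose, tdiB, a prenyltransferase gene, from 0.388 ± 0.141 to 428 ± 305 CPM (log2 change 10.10, SE 0.65, adjusted p 2.58e-08). Higher were also 9 of 11 monodictyphenone genes (10 adjusted over the list alone), 3 of 3 asperthecin genes, 4 of 4 emericellamide genes, 3 of 5 orsellinic acid genes and 6 of 11 genes of the benzaldehyde derivative cluster. Between starved cultures A and B the members differed by a median of 8.85-fold in that cluster, 4.05-fold in the orsellinic acid and 3.02-fold in the terrequinone cluster, all higher in B. In the penicillin cluster the synthase gene ipnA (log2 change 1.09, SE 0.38, adjusted p 0.0219) and aatA rose, while acvA was not called. Without starved A (log2 change 0.24) or without grown A (0.91) ipnA was not called. The gene apdA, the hybrid polyketide synthase gene of the aspyridone cluster, fell from 132 ± 7.58 to 0.606 ± 0.140 CPM (log2 change -7.76, SE 0.47, adjusted p 1.49e-08). In the cichorine cluster 3 of 5 genes were lower, and in the austinol clusters 4 of 11 were lower and 2 higher.

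Among regulators, laeA, a global regulator of secondary metabolism, rose from 49.4 ± 2.19 to 207 ± 24.0 CPM (log2 change 2.07, SE 0.10, adjusted p 2.70e-09), and velB fell (log2 change -0.62, SE 0.11, adjusted p 2.42e-04). Of the asexual development and conidial genes 8 of 14 were higher and 3 lower, with a median log2 change of 0.57 and no call by camera. Among those higher were brlA, the regulator of conidiophore formation, from 2.74 ± 0.349 to 365 ± 26.3 CPM, and rodA, the hydrophobin gene of the spore wall, from 0.172 ± 0.128 to 875 ± 279 CPM (log2 change 12.28, SE 0.82, adjusted p 3.90e-08). The catalase-peroxidase gene cpeA rose (log2 change 6.50, SE 0.21, adjusted p 1.32e-10), with 4 of 9 oxidative stress genes higher and 3 lower. The largest rise by the naming rule was that of AN6476, from 0.0791 ± 0.0735 to 2200.4 ± 439.5 CPM (log2 change 14.71, SE 0.84, adjusted p 9.57e-09). AN9128, at 0 counts in the grown cultures, was at least 318-fold higher. In all, 7358 genes were called, 3886 higher and 3472 lower, which is 52.8% higher against 69.8% with library totals.

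Pre-starved refed cultures were compared with starved cultures to follow the return to growth within 2 h of refeeding. The nitrate and sugar genes came back. The gene niaD rose to 2424 ± 111 CPM (log2 change 9.78, SE 0.25, adjusted p 5.22e-11), and all 5 nitrate genes, all 11 glycolysis genes and all 3 ammonium genes were higher. The adjusted p of camera was 0.00184, 3.45e-05 and 0.0221, and an adjusted p of 0.511 for each with the estimated correlation. In the sterigmatocystin cluster aflR fell back to 0.289 ± 0.00451 CPM (log2 change -6.19, SE 0.41, adjusted p 2.71e-08), with 8 members lower and 5 higher, stcA among the latter (log2 change 3.28, SE 0.27, adjusted p 2.21e-07). The 3 terrequinone genes fell, tdiB to 2.36 ± 0.916 CPM (log2 change -7.50, SE 0.55, adjusted p 7.09e-08). The penicillin genes acvA (log2 change 3.21, SE 0.41, adjusted p 1.30e-05) and ipnA (log2 change 1.54, SE 0.38, adjusted p 0.00254) rose on refeeding, while aatA fell. The gene apdA rose to 136 ± 55.4 CPM (log2 change 7.81, SE 0.47, adjusted p 1.16e-08), and 7 of 11 austinol genes, 4 of 6 aspyridone genes and 4 of 7 asperfuranone genes were higher.

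Genes raised by starvation differed in how far they fell on refeeding. The protease gene prtA stood at 1135 ± 123 CPM (log2 change -0.45, SE 0.22, adjusted p 0.0802) and was not called, while pepJ fell to 9.36 ± 4.6 CPM (log2 change -5.38, SE 0.39, adjusted p 7.00e-08) and the chitinase gene chiB fell (log2 change -4.80, SE 0.13, adjusted p 6.10e-11). The marker rodA stood at 1820.2 ± 284 CPM, above its starved level in the mean but not called (log2 change 1.06, SE 0.47, adjusted p 0.0557), and dewA, another spore hydrophobin gene, fell (log2 change -7.45, SE 0.53, adjusted p 6.22e-08). Of the heat shock genes 5 of 6 were higher, hsp104 among them (log2 change 2.74, SE 0.17, adjusted p 1.54e-08). The 7649 genes called comprised 3530 higher and 4119 lower, 46.1% higher against 27.8% with library totals.

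Naive refed cultures were compared with grown cultures to see what a change to fresh medium did without any starvation. The refed cultures were also 2 h older, and no group stayed in its first medium for that time. Effects of fresh medium and of the later harvest therefore cannot be told apart here. By edgeR 311 genes were called, 213 higher and 98 lower. DESeq2 called 610, the 32 libraries with duplicate correlation 581 and a fit of these groups alone 759. The largest rises were those of AN9320, from 2.56 ± 0.899 to 24.2 ± 3.15 CPM (log2 change 3.23, SE 0.44, adjusted p 0.00200), and AN7549 (log2 change 2.73, SE 0.33, adjusted p 8.49e-04). AN7323 fell from 79.2 ± 6.93 to 9.53 ± 2.71 CPM (log2 change -3.06, SE 0.24, adjusted p 8.90e-05), and its neighbour in number AN7322 fell alike (log2 change -3.10, SE 0.23, adjusted p 8.90e-05). The gene sidI, which acts in siderophore synthesis, fell (log2 change -1.63, SE 0.20, adjusted p 8.49e-04). Of 199 list members 4 were called by edgeR (6 by DESeq2, 20 at an unadjusted edgeR p under 0.05): atg1, a kinase gene of autophagy (log2 change 0.44, SE 0.097, adjusted p 0.0295), the arginase gene agaA (log2 change 0.77, SE 0.17, adjusted p 0.0295), sodB, a superoxide dismutase gene (log2 change 0.50, SE 0.10, adjusted p 0.0210), and rosA, a repressor of sexual development (log2 change 1.23, SE 0.30, adjusted p 0.0458). The genes aflR (log2 change 0.44, SE 0.52, adjusted p 0.739), stcA and stcU were not called. Leaving out 1 culture moved the number of genes called to 96 without grown A, 64 without grown B, 128 without naive refed A and 93 without naive refed B. None of the 4 list members was called without any 1 of these cultures, rosA for example at a log2 change of 0.89 without naive refed A and 1.5 without naive refed B.

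**Figure D2:**
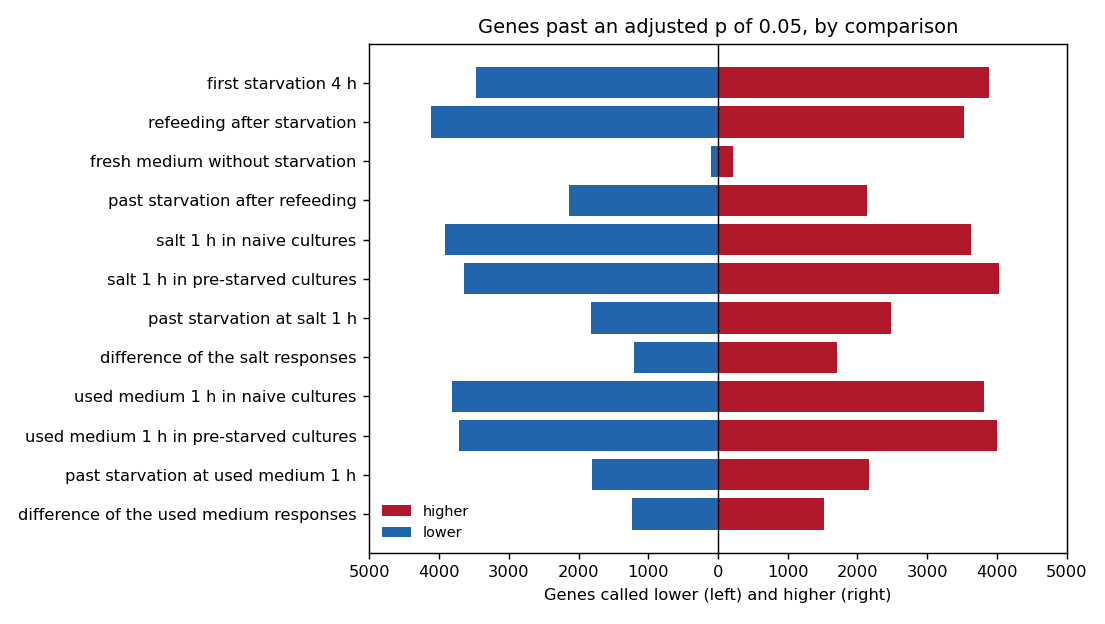
Bars give, for each of the 12 comparisons on the y axis, the number of genes called higher (right) and lower (left) on the x axis, at an adjusted p under 0.05 from edgeR's quasi-likelihood test. In the comparison of fresh medium without starvation, in which refed cultures were also 2 h older, 311 genes were called. In each comparison of a 1 h move into salt or used medium at least 7548 were called.

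Pre-starved refed cultures were compared with naive refed cultures to find what the past starvation, with the shorter growth before it, left behind after both had spent 2 h in fresh medium. The hydrophobin gene rodA stood 0.301 ± 0.0101 against 1820.2 ± 284 CPM (log2 change 12.55, SE 0.80, adjusted p 4.14e-07), and brlA was higher too (log2 change 4.64, SE 0.31, adjusted p 6.06e-07). Of the asexual development and conidial genes as a list 5 of 14 were higher and 2 lower, with no call by camera. Of the autolysis genes 4 of 5 were higher, prtA at 1135 ± 123 against 46.4 ± 2.86 CPM (log2 change 4.61, SE 0.26, adjusted p 1.62e-07) and pepJ (log2 change 5.01, SE 0.51, adjusted p 1.45e-05), and chiB was not called. Among secondary metabolite clusters all 3 penicillin genes were higher, acvA (log2 change 3.89, SE 0.44, adjusted p 3.04e-05) and ipnA (log2 change 3.31, SE 0.41, adjusted p 6.40e-05) for example. All 5 orsellinic acid genes were higher, orsC, a tyrosinase gene, at 14.5 ± 11 against 0.479 ± 0.227 CPM (log2 change 4.91, SE 0.86, adjusted p 7.45e-04), as were the 3 terrequinone genes, 2 of 3 asperthecin genes and 5 of 11 austinol genes. In pre-starved refed cultures all orsellinic acid and terrequinone genes were higher in B than in A, by a median of 4.64-fold and 3.03-fold. The sterigmatocystin genes had 2 higher and 4 lower of 17 (3 and 5 adjusted over the list alone), with stcA higher (log2 change 1.61, SE 0.25, adjusted p 3.34e-04) and aflR not called (log2 change -0.32, SE 0.49, adjusted p 0.628).

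Nitrate, ammonium and glycolysis genes also differed between pre-starved and naive refed cultures. All 5 nitrate genes, 2 of 3 ammonium genes and 8 of 11 glycolysis genes were higher, gltA, the glutamate synthase gene, most (log2 change 2.29, SE 0.21, adjusted p 6.79e-06) and niaD less (log2 change 0.52, SE 0.17, adjusted p 0.0277). The call of niaD was lost when any 1 of the 4 cultures was left out (log2 change 0.46 without naive refed A, 0.57 without naive refed B). Of the 4 autophagy genes 3 were lower (4 adjusted over the list alone), atg1 most (log2 change -1.35, SE 0.098, adjusted p 1.07e-06), and mcrA, a repressor of secondary metabolite clusters, was lower (log2 change -1.52, SE 0.10, adjusted p 6.73e-07). Camera called penicillin at an adjusted p of 0.0215, asperthecin at 0.0344, glycolysis at 0.0215, and orsellinic acid, nitrate, ammonium, autolysis and autophagy each at 0.0344. With the estimated correlation the adjusted p was 0.414 for orsellinic acid and 0.409 for the other lists named. Among the largest falls, AN8928 stood at 0.735 ± 0.231 against 142 ± 26.9 CPM (log2 change -7.59, SE 0.54, adjusted p 8.81e-07) and AN3229 at 1.01 ± 0.0943 against 97.0 ± 32.7 CPM (log2 change -6.58, SE 0.32, adjusted p 8.03e-08). Of 4277 genes called 2142 were higher and 2135 lower, 50.1% higher against 31.7% with library totals.

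The 3886 genes raised and the 3472 lowered by the first starvation were then set against the calls left after refeeding. Of the raised genes 776 were still higher in pre-starved than in naive cultures, where independent lists would share 831, and 848 were lower. Of the lowered genes 831 were still lower, against 739.6 for independent lists, and 921 were higher. The genes rodA, brlA, prtA and pepJ were in the first set, while niaD and gdhA, which fell under starvation, were higher after refeeding. Across genes, which are not independent replicates, the log2 changes of the comparisons had a Pearson r of 0.177.

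Naive salt cultures were compared with naive refed cultures for the first response to 1 h without carbon and nitrogen. Nitrate and sugar genes fell again. The gene niaD went from 1695 ± 90.4 to 16.5 ± 1.98 CPM (log2 change -6.68, SE 0.22, adjusted p 1.17e-10), with 4 of 5 nitrate genes lower, and all 11 glycolysis genes were lower, pfkA, phosphofructokinase, from 4449 ± 273 to 133 ± 27.7 CPM (log2 change -5.07, SE 0.21, adjusted p 4.94e-10). Camera's adjusted p was 0.0480 and 0.00263, and an adjusted p of 0.827 for both with the estimated correlation. Some genes for the use of other sources rose: the proline catabolism genes prnD (log2 change 7.44, SE 0.40, adjusted p 4.11e-09) and prnC (log2 change 7.18, SE 0.20, adjusted p 6.02e-11), the alcohol dehydrogenase gene alcA (log2 change 2.42, SE 0.70, adjusted p 0.00696) and 5 of 8 gluconeogenesis and acetate genes, acuD, isocitrate lyase, for example (log2 change 2.34, SE 0.40, adjusted p 1.65e-04). In the list of nitrogen regulation and alternative nitrogen use, which holds the proline genes, 6 of 16 genes were higher and 9 lower, with a median log2 change of -0.96 and no call by camera. The gene aflR rose to 3.48 ± 1.36 CPM (log2 change 3.26, SE 0.39, adjusted p 6.66e-06), with 7 cluster genes higher and 6 lower, stcA among the lower (log2 change -0.77, SE 0.25, adjusted p 0.0146). Not called were stcA without naive salt A (log2 change -0.62) or naive refed B (-0.72) and alcA without naive refed B (2.30). Of the histone genes 5 of 6 were lower, hhfA most (log2 change -2.60, SE 0.12, adjusted p 1.65e-09), and of the chromatin regulators 6 of 8, hepA, the heterochromatin protein gene, among them (log2 change -1.95, SE 0.20, adjusted p 1.63e-06). Camera called none of the gluconeogenesis, histone and chromatin lists, and 75.3% of all tested genes were called in this comparison. AN9010 rose from 0.144 ± 0.0648 to 339 ± 46.0 CPM (log2 change 11.18, SE 0.38, adjusted p 1.43e-10), and AN2544, at 0 counts in naive refed cultures, was at least 349-fold higher. There were 7548 genes called, 3633 higher and 3915 lower, 48.1% higher against 64.4% with library totals. With the first starvation of 4 h this response shared 2886 higher genes, against 1409 for independent lists, and 2943 lower genes, against 1356.

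Pre-starved salt cultures were compared with pre-starved refed cultures for the response to the second starvation. The gene aflR rose from 0.289 ± 0.00451 to 7.31 ± 0.956 CPM (log2 change 4.65, SE 0.40, adjusted p 2.88e-07) while stcA fell (log2 change -2.98, SE 0.26, adjusted p 4.28e-07), and the cluster had 7 genes higher and 7 lower. All 11 tested austinol genes fell, AN8381 for example (log2 change -5.25, SE 0.98, adjusted p 4.41e-04), as did 5 of 7 asperfuranone genes, afoE, a polyketide synthase gene, for example (log2 change -8.60, SE 0.51, adjusted p 9.65e-09), and 3 of 5 orsellinic acid genes (2 adjusted over the list alone). Nitrate (5 of 5), ammonium (3 of 3), glycolysis (11 of 11) and heat shock genes (5 of 6) were lower, niaD (log2 change -8.67, SE 0.24, adjusted p 5.26e-11) and the mitochondrial chaperone gene hsp60 (log2 change -3.82, SE 0.24, adjusted p 1.53e-08) for example. Camera's adjusted p for austinol, nitrate, ammonium, glycolysis and heat shock genes was 0.0299, 0.00515, 0.0299, 4.62e-05 and 0.0390. With the estimated correlation the adjusted p was 0.769 for heat shock genes and 0.526 for the other lists named. The spore wall gene rodA fell from 1820.2 ± 284 to 278 ± 192 CPM (log2 change -2.71, SE 0.49, adjusted p 2.64e-04), and vosA, a velvet regulator gene of spore maturation, rose (log2 change 2.94, SE 0.13, adjusted p 8.49e-10). All 4 sexual development regulators were higher, steA for example (log2 change 1.53, SE 0.15, adjusted p 1.05e-06). AN5421, also among the largest rises, went from 1.35 ± 0.795 to 591 ± 284 CPM (log2 change 8.77, SE 0.44, adjusted p 2.35e-09). There were 7672 genes called, 4027 higher and 3645 lower, 52.5% higher against 72.8% with library totals.

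Pre-starved and naive cultures were compared after the same hour in salt to ask whether the earlier starvation changed the level reached. AN8953 stood at 3904 ± 1051 against 61.0 ± 2.97 CPM (log2 change 6.0, SE 0.29, adjusted p 1.60e-07), AN3388 at 78.4 ± 8.79 against 0.927 ± 0.138 CPM (log2 change 6.40, SE 0.42, adjusted p 9.52e-07), and rodA at 278 ± 192 against 2.73 ± 0.534 CPM (log2 change 6.67, SE 0.60, adjusted p 9.03e-06). The activator gene aflR was 7.31 ± 0.956 CPM in pre-starved and 3.48 ± 1.36 CPM in naive cultures (log2 change 1.07, SE 0.30, adjusted p 0.0130), while the cluster as a list had 2 genes higher and 3 lower (1 and 3 adjusted over the list alone), and stcA and stcU were not called. Without naive salt B (log2 change 0.72) or pre-starved salt A (0.93) aflR was not called. In the penicillin cluster ipnA (log2 change 2.45, SE 0.39, adjusted p 3.86e-04) and acvA (log2 change 2.38, SE 0.43, adjusted p 8.67e-04) were higher, and 6 of 11 monodictyphenone genes were higher. The regulator genes laeA, at 169.6 ± 4.15 against 60.7 ± 0.569 CPM (log2 change 1.48, SE 0.100, adjusted p 1.25e-06), and veA (log2 change 0.66, SE 0.12, adjusted p 7.74e-04) were higher. Of the chromatin regulators 6 of 8 were higher, hepA at 55.7 ± 16.2 against 16.5 ± 2.66 CPM (log2 change 1.75, SE 0.20, adjusted p 3.82e-05) and the histone methyltransferase gene clrD (log2 change 1.28, SE 0.24, adjusted p 0.00116). Autolysis genes were higher in 4 of 5 (5 adjusted over the list alone), pepJ most (log2 change 2.65, SE 0.35, adjusted p 1.00e-04), and all 4 sexual development regulators were higher.

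Other lists were lower in pre-starved than in naive salt cultures. These were 4 of 5 nitrate genes, niaD for example (log2 change -1.46, SE 0.18, adjusted p 6.06e-05), 5 of 8 gluconeogenesis and acetate genes, acuD at 73.6 ± 29.0 against 449.7 ± 98.1 CPM (log2 change -2.61, SE 0.41, adjusted p 3.23e-04), and 4 of 6 heat shock genes (5 adjusted over the list alone), hsp104 for example (log2 change -1.18, SE 0.16, adjusted p 1.29e-04). The catalase gene catB was lower too (log2 change -1.86, SE 0.14, adjusted p 2.78e-06). By camera the adjusted p was 0.0286 for each of the nitrate, gluconeogenesis, heat shock, autolysis and chromatin lists. With the estimated correlation the adjusted p was 0.361 for chromatin regulators and 0.499 for the other lists named. Of 4306 genes called 2479 were higher and 1827 lower, 57.6% higher against 44.8% with RLE size factors. Of the higher genes 1039 (41.9%) had already been higher after refeeding, as rodA and AN8953 were, and for 874 the response itself differed in the same direction. Of the lower genes 861 (47.1%) had already been lower, and for 613 the response differed in the same direction.

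The difference of the salt responses, the change into salt in pre-starved cultures minus that in naive cultures, tested whether the response itself changed. The cluster gene aflS, next to aflR, went from 4.91 ± 0.202 to 21.3 ± 1.09 CPM in pre-starved and from 13.3 ± 0.611 to 15.3 ± 3.45 CPM in naive cultures (log2 change 1.92, SE 0.25, adjusted p 2.62e-04), while aflR was not called (log2 change 1.39, SE 0.58, adjusted p 0.0912) and stcA was lower (log2 change -2.21, SE 0.36, adjusted p 9.58e-04). The regulator genes laeA (log2 change 0.85, SE 0.14, adjusted p 9.70e-04) and mcrA (log2 change 1.08, SE 0.14, adjusted p 2.88e-04) responded more positively, with 3 of 5 secondary metabolism regulators higher. So did hepA (log2 change 1.68, SE 0.27, adjusted p 9.65e-04), the autophagy kinase gene atg1 (log2 change 1.49, SE 0.14, adjusted p 3.15e-05) and 3 of 6 histone genes. AN3388 rose from 0.861 ± 0.615 to 78.4 ± 8.79 CPM in pre-starved cultures and from 0.240 ± 0.0285 to 0.927 ± 0.138 CPM in naive ones (log2 change 4.57, SE 0.80, adjusted p 0.00147). Differences in the level after refeeding enter this test. The gene stcA had been higher in pre-starved than in naive cultures after refeeding, and in salt it was not called between them. After refeeding mcrA (log2 change -1.52) and atg1 (-1.35) had been lower in pre-starved than in naive cultures, as aflS had, and in salt mcrA was still lower (-0.44; -0.32 and not called without naive salt B). For AN3229 the difference (log2 change 5.93, SE 0.39, adjusted p 7.03e-06) came mostly from its level after refeeding, 1.01 ± 0.0943 CPM in pre-starved and 97.0 ± 32.7 CPM in naive cultures. More negative in pre-starved cultures were 8 of 11 glycolysis genes (10 adjusted over the list alone), 4 of 5 nitrate genes, 2 of 3 ammonium genes, 5 of 6 heat shock genes, 4 of 8 gluconeogenesis genes and 3 of 11 austinol genes. Examples were gltA (log2 change -2.70, SE 0.29, adjusted p 8.98e-05), acuD (log2 change -3.28, SE 0.56, adjusted p 0.00123) and rodA (log2 change -5.88, SE 0.87, adjusted p 5.18e-04). Of these gltA (log2 change 2.29) and rodA (12.55) had been higher in pre-starved cultures after refeeding, and rodA was still higher in salt (6.67). The median log2 change of pre-starved against naive cultures went from 1.45 after refeeding to -0.40 in salt for the ammonium list and from 0.82 to -0.43 for the glycolysis list, both not called by camera in salt. Without naive salt A, aflR was called (log2 change 1.86). Camera's adjusted p for the glycolysis, nitrate, ammonium, heat shock, gluconeogenesis and austinol lists was 2.37e-05, 3.17e-04, 0.00222, 4.46e-04, 0.00327 and 0.00163, and 0.0185 for the regulators. With the estimated correlation the adjusted p was 0.468 for gluconeogenesis genes and 0.263 for the other lists named. Of 2913 genes called 1709 had a more positive and 1204 a more negative response, 58.7% more positive against 44.5% with RLE size factors and 77.8% with library totals.

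Naive used-medium cultures were compared with naive refed cultures for the first response to medium in which the fungus had already grown. The terrequinone genes rose, tdiB from 0.495 ± 0.131 to 186 ± 5.09 CPM (log2 change 8.55, SE 0.61, adjusted p 5.01e-08), with all 3 tested members higher. So did all 3 penicillin genes, ipnA from 6.80 ± 0.830 to 129 ± 1.98 CPM (log2 change 4.24, SE 0.43, adjusted p 1.33e-06), 4 of 5 orsellinic acid genes, orsB for example (log2 change 5.94, SE 0.92, adjusted p 6.68e-05), 4 of 4 emericellamide genes and 3 of 3 asperthecin genes. The gene aflR reached 11.9 ± 0.202 CPM (log2 change 5.03, SE 0.39, adjusted p 1.19e-07), with 9 cluster genes higher and 5 lower, stcA among the lower (log2 change -1.23, SE 0.26, adjusted p 9.08e-04). The alcohol dehydrogenase gene alcA rose from 378 ± 51.1 to 16831 ± 10269 CPM (log2 change 5.48, SE 0.80, adjusted p 4.09e-05), with 24092 CPM in culture A and 9569 CPM in culture B of the used-medium group, and aldA, aldehyde dehydrogenase, rose as well (log2 change 4.64, SE 0.38, adjusted p 1.72e-07). In the alcohol use list 3 of 4 genes were higher, and creA, the carbon repressor gene, was not called (log2 change -0.22, SE 0.32, adjusted p 0.534; log2 change 0.14 with library totals). All 11 glycolysis genes fell (camera's adjusted p 0.00146, and an adjusted p of 0.629 with the estimated correlation), as did 4 of 5 nitrate genes, niaD for example (log2 change -7.07, SE 0.22, adjusted p 8.03e-11). Of the asexual development genes 10 of 14 were higher, and rodA reached 1.53 ± 0.240 CPM (log2 change 2.34, SE 0.78, adjusted p 0.0158). AN6782 rose from 0.0600 ± 0.0156 to 927 ± 401 CPM (log2 change 13.86, SE 0.82, adjusted p 1.01e-08). There were 7632 genes called, 3819 higher and 3813 lower, 50.0% higher against 60.8% with library totals.

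In pre-starved cultures the move into used medium raised 3 of 3 terrequinone, 3 of 3 penicillin and 1 of 4 emericellamide genes. Of the orsellinic acid genes 1 of 5 were higher (median log2 change 0.45, against 5.01 in naive cultures) and of the asperthecin genes 1 of 3 (0.65, against 2.06). The gene tdiB went from 2.36 ± 0.916 to 1261 ± 113 CPM (log2 change 9.06, SE 0.58, adjusted p 1.83e-08), ipnA from 67.4 ± 19.0 to 474 ± 81.8 CPM (log2 change 2.81, SE 0.39, adjusted p 2.55e-05) and aflR from 0.289 ± 0.00451 to 30.7 ± 11.6 CPM (log2 change 6.72, SE 0.41, adjusted p 1.24e-08). The sterigmatocystin list had 9 genes higher and 6 lower, stcA (log2 change -3.40, SE 0.27, adjusted p 1.54e-07) and stcU (log2 change -5.59, SE 0.66, adjusted p 6.12e-06) among the lower. The genes alcA (log2 change 7.38, SE 0.87, adjusted p 6.03e-06), aldA (log2 change 6.02, SE 0.40, adjusted p 2.74e-08) and alcR, the activator of both (log2 change 4.29, SE 0.30, adjusted p 4.00e-08), rose. Of the benzaldehyde derivative cluster 7 of 11 genes were higher (2 adjusted over the list alone), but its cultures A and B differed by a median of 19.0-fold in used medium, all members higher in A, and of 4.61-fold after refeeding, all higher in B. Austinol genes were lower in 10 of 11, nitrate genes in 5 of 5, ammonium genes in 3 of 3 and glycolysis genes in 11 of 11. For these lists camera's adjusted p was 0.0377, 0.00721, 0.0377 and 1.05e-04, and an adjusted p of 0.572 for each with the estimated correlation. The protease gene prtA fell from 1135 ± 123 to 424 ± 116 CPM (log2 change -1.42, SE 0.23, adjusted p 8.33e-05) and rodA fell to 154 ± 95.1 CPM (log2 change -3.56, SE 0.51, adjusted p 3.46e-05). AN0216, at 0 counts in pre-starved used-medium cultures, was at least 837-fold lower there than after refeeding. There were 7711 genes called, 3995 higher and 3716 lower, 51.8% higher against 67.8% with library totals.

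**Figure D3:**
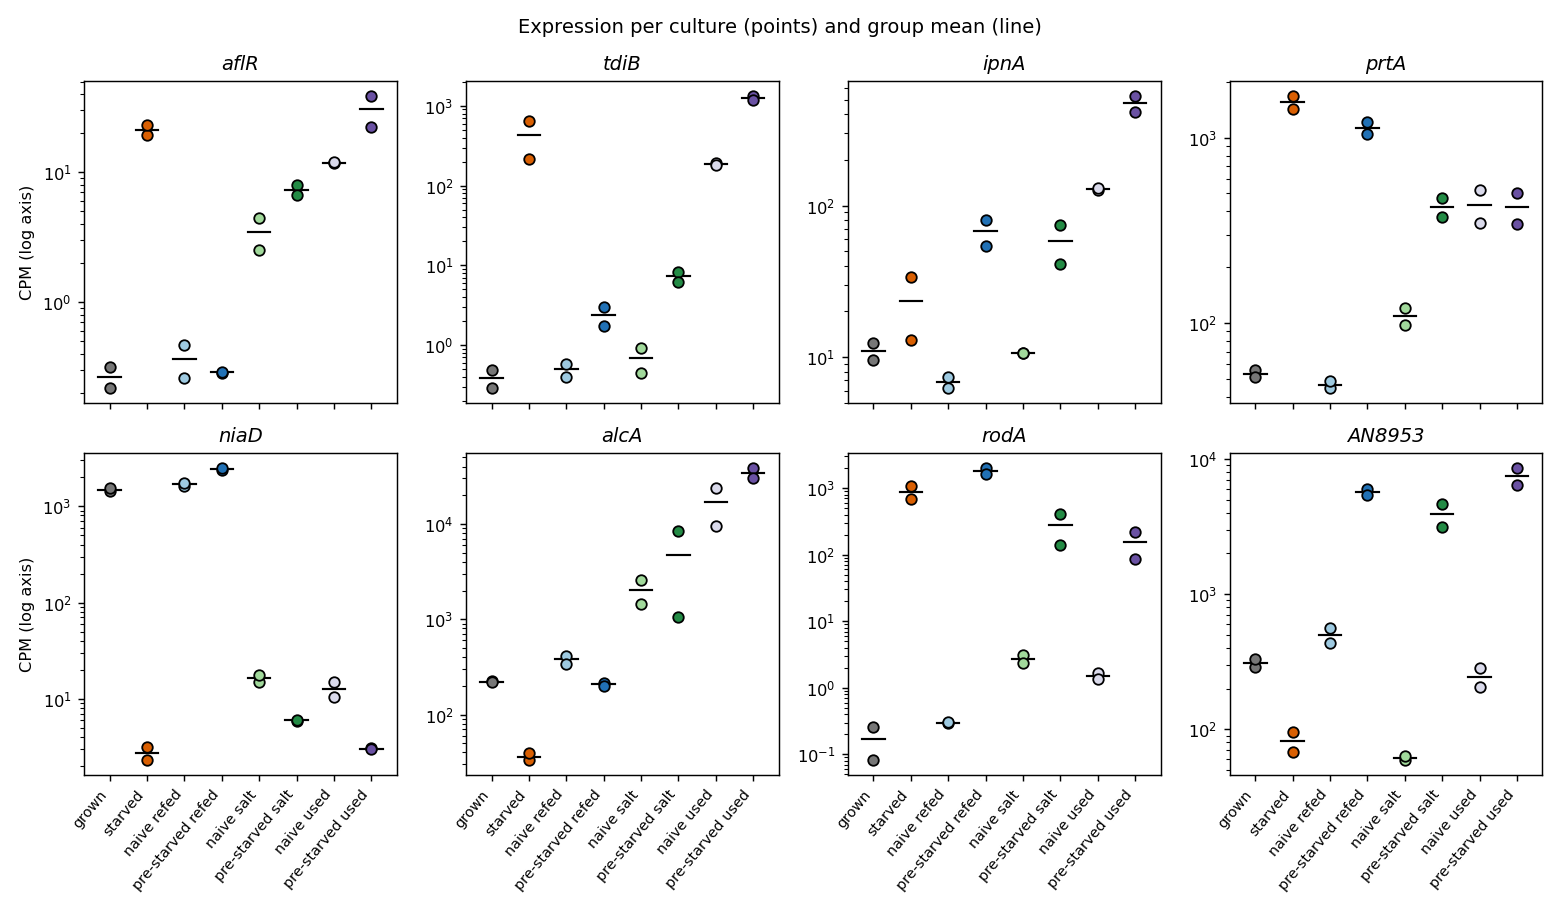
Each panel plots 1 gene, with CPM on a logarithmic y axis, the 8 groups on the x axis, a point per culture and a line at the group mean. The genes aflR, tdiB and ipnA were highest in pre-starved used-medium cultures, and AN8953 was higher in each pre-starved group than in its naive counterpart.

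Pre-starved and naive cultures were also compared after the same hour in used medium. All 3 terrequinone genes were higher in pre-starved cultures, tdiB at 1261 ± 113 against 186 ± 5.09 CPM (log2 change 2.76, SE 0.43, adjusted p 3.78e-04), and all 3 penicillin genes, ipnA at 474 ± 81.8 against 129 ± 1.98 CPM (log2 change 1.88, SE 0.38, adjusted p 0.00204). The activator gene aflR stood at 30.7 ± 11.6 against 11.9 ± 0.202 CPM (log2 change 1.37, SE 0.30, adjusted p 0.00327) and aflS was higher (log2 change 0.96, SE 0.18, adjusted p 0.00112), with 3 cluster genes higher and 2 lower, and stcA and stcU not called. AN8953 (log2 change 4.94, SE 0.28, adjusted p 4.64e-07), AN3388 (log2 change 6.37, SE 0.41, adjusted p 1.33e-06) and AN10891, at 702 ± 311 against 17.7 ± 10.8 CPM (log2 change 5.32, SE 0.53, adjusted p 2.00e-05), were among the largest rises, together with rodA (log2 change 6.65, SE 0.62, adjusted p 1.23e-05). The aldehyde dehydrogenase gene aldA was higher (log2 change 0.94, SE 0.33, adjusted p 0.0380), whereas alcA, at 38814 and 30274 CPM in pre-starved and 24092 and 9569 CPM in naive cultures, was not called (log2 change 1.04, SE 0.67, adjusted p 0.239). Nor was aldA without naive used B (log2 change 0.61), pre-starved used A (0.77) or pre-starved used B (1.09). Chromatin regulators were higher in 5 of 8, hepA for example (log2 change 1.47, SE 0.20, adjusted p 1.5e-04). Nitrate genes were lower in 4 of 5, niaD for example (log2 change -2.05, SE 0.19, adjusted p 1.09e-05; camera's adjusted p 0.0259, and an adjusted p of 0.600 with the estimated correlation), and AN3225 was lower at 0.272 ± 0.0494 against 22.3 ± 0.0503 CPM (log2 change -6.35, SE 0.23, adjusted p 1.66e-08). Of 3978 genes called 2167 were higher and 1811 lower, and a fit of these groups alone called fewer. Of the higher genes 938 (43.3%) had already been higher after refeeding, and for 718 the response differed in the same direction.

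The difference of the used medium responses compared the change into used medium between pre-starved and naive cultures. The genes aflR (log2 change 1.69, SE 0.58, adjusted p 0.0464) and aflS (log2 change 2.40, SE 0.25, adjusted p 6.85e-05) responded more positively in pre-starved cultures, with 4 sterigmatocystin genes more positive and 2 more negative (4 and 4 adjusted over the list alone), stcA among the latter (log2 change -2.17, SE 0.37, adjusted p 0.00129). The genes aldA (log2 change 1.38, SE 0.46, adjusted p 0.0422), chiB (log2 change 1.26, SE 0.16, adjusted p 2.41e-04) and hepA (log2 change 1.40, SE 0.27, adjusted p 0.00307) responded more positively, and so did 3 of 6 histone genes. More negative in pre-starved cultures were 2 of 3 penicillin genes (3 adjusted over the list alone), acvA for example (log2 change -2.10, SE 0.56, adjusted p 0.0157), 3 of 5 orsellinic acid genes, orsC for example (log2 change -4.56, SE 1.08, adjusted p 0.00846), and 2 of 3 asperthecin genes. When 1 culture was left out, aldA kept its call only without naive used A (others 1.07 to 1.54 on the log2 scale), and aflR only without naive refed B or pre-starved used B (others 1.22 to 1.72). With technical library 1 alone aflR had a log2 change of 3.74, and with technical library 2 alone it was not called (0.37). With RLE size factors neither aflR (1.66) nor aldA (1.34) was called. The call of acvA was lost without naive refed B (-2.03), naive used B (-1.65) or pre-starved refed A (-1.64). The penicillin, orsellinic acid and asperthecin clusters had started higher after refeeding, as orsC had at 14.5 ± 11 against 0.479 ± 0.227 CPM. So had stcA, which was not called between pre-starved and naive cultures in used medium. More negative were also all 5 nitrate, 3 ammonium and 6 heat shock genes, 6 of 11 glycolysis genes, 5 of 11 austinol genes and 3 of 5 trehalose and glycerol genes, with niaD (log2 change -2.57, SE 0.25, adjusted p 4.32e-05) and the trehalase gene treB (log2 change -1.37, SE 0.19, adjusted p 3.25e-04) as examples. The adjusted p of camera was 0.0428 for asperthecin, 1.97e-04 for nitrate, 0.00263 for ammonium, 0.00169 for heat shock, 6.77e-04 for glycolysis, 0.00938 for austinol and 0.0332 for trehalose genes. With the estimated correlation the adjusted p was 0.389 for nitrate, 0.481 for trehalose and 0.416 for the other lists named. After refeeding the nitrate, ammonium and glycolysis lists had been higher in pre-starved than in naive cultures. After the hour in used medium camera, at its preset correlation, called only the nitrate list between these cultures. Of 2743 genes called 1514 had a more positive and 1229 a more negative response, 55.2% more positive against 75.1% with library totals.

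**Figure D4:**
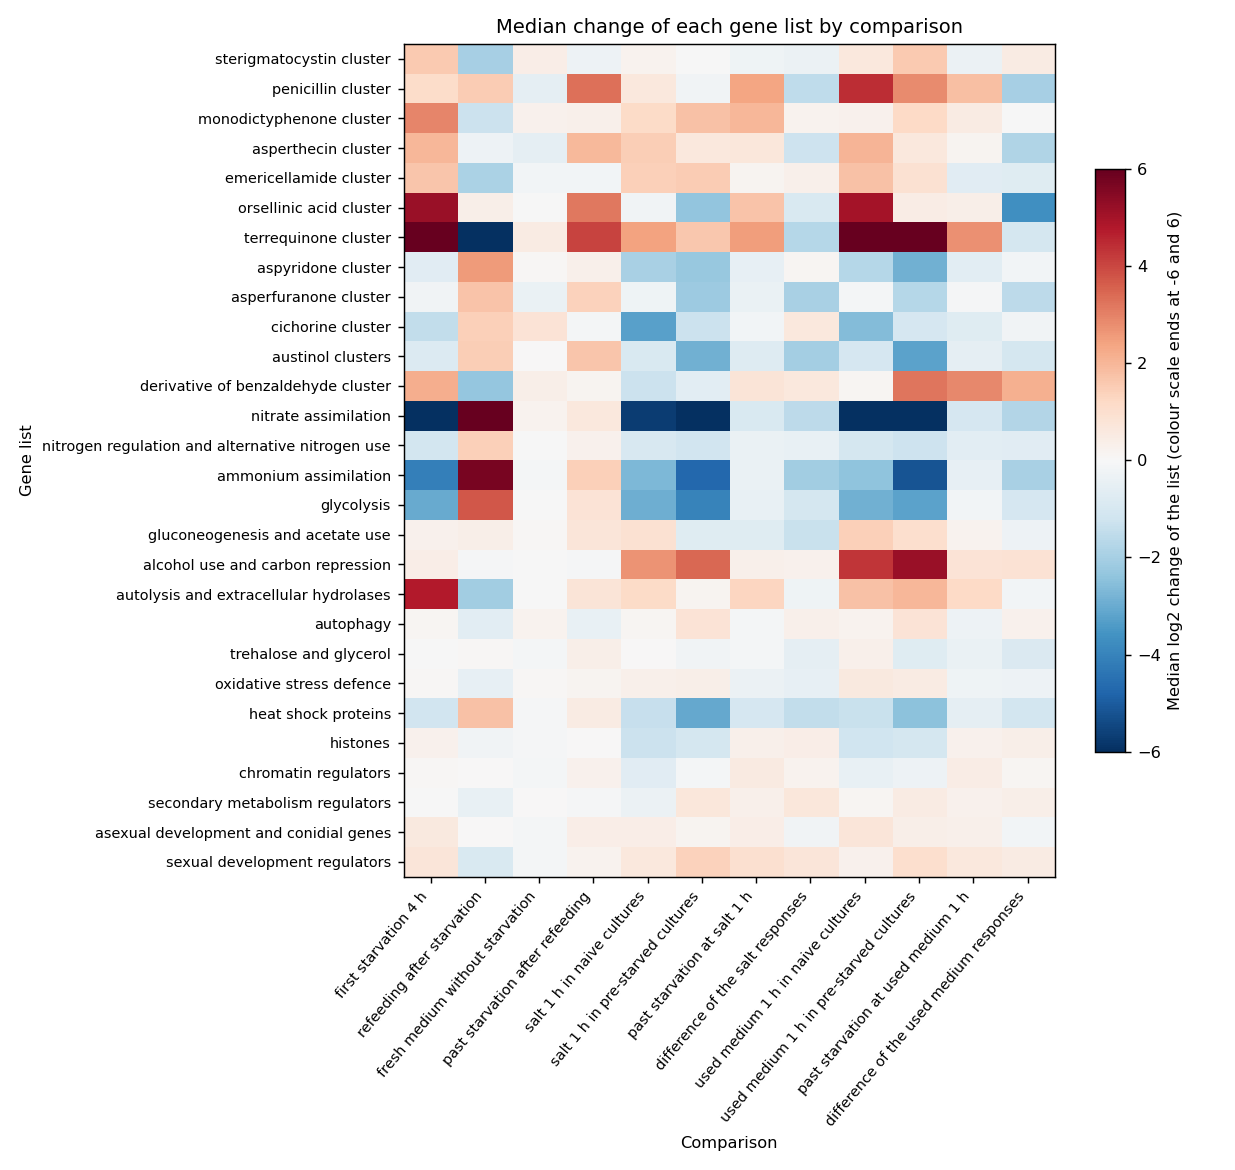
Colours give the median log2 fold change of the tested members of each gene list (y axis) in each of the 12 comparisons (x axis), red for higher and blue for lower. Nitrate, ammonium and glycolysis lists alternate with the medium, and the terrequinone list is red after starvation and in used medium.

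Genes induced more strongly on renewed starvation were defined as those called positive in the pre-starved response, in the pre-starved against naive comparison and in the difference of the responses. Named members of the salt set were aflS, veA and laeA, of which veA went from 296 ± 32.2 to 789 ± 73.9 CPM in pre-starved and from 299.7 ± 27.1 to 500.4 ± 1.31 CPM in naive cultures. The set also held the chitinase gene chiB, vosA, which went from 17.4 ± 0.371 to 133 ± 1.22 CPM in pre-starved and from 19.8 ± 0.850 to 60.0 ± 4.36 CPM in naive cultures, and the developmental regulators flbE, nsdD, steA and stuA. In used medium the set held aflR, aflS, chiB, veA, vosA and aldA. Few cluster genes were in the sets. In salt they were 1 of 17 tested sterigmatocystin genes (aflS) and 1 of 7 asperfuranone genes (afoB). In used medium they were 2 of 17 sterigmatocystin genes. The other clusters had 0 in either set, penicillin and terrequinone among them. Over all 10022 tested genes the sets held 326 in salt and 236 in used medium. In salt 326 genes were induced more strongly, 171 of them with a difference of at least 2-fold, and 332 met the mirror rule for repression. In used medium the numbers were 236, 130 and 357. The balance of the sets turned with the scaling. In salt 194 were induced and 445 repressed more strongly with RLE size factors, and 839 and 207 with library totals. In used medium the numbers were 177 and 387, and 580 and 245. Leaving out 1 culture brought the induced set in salt to 206 without pre-starved refed B, 214 without naive salt A and 208 without pre-starved salt B, and the repressed set to 220 without naive salt B. The induced set in used medium went to 147 without naive used A, 156 without naive used B, 148 without pre-starved refed B and 135 without pre-starved used B.

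The effect of the past starvation was compared between salt and used medium, which share no library. Higher in pre-starved cultures in both media were 1810 genes, where independent lists would share 536, and lower in both were 1260, where independent lists would share 330.1. The genes aflR, aflS, laeA, veA, hepA, ipnA, AN8953 and rodA were higher in both, and niaD, apdA and AN3225 lower in both. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.762.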

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

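The tests of library scaling, of a share of mycelium left starved, of leftover mRNA and of counting noise were chosen only after the result was seen. A test of leftover mRNA set out before had a limit of 5% of the set, and 49 genes (6.31%) were called above their starved level, which by that limit argued against leftover mRNA. It was replaced because the limit took a bound on false calls among the calls for one among all genes tested. The results in this part were marked because a test of the difference itself found that the response to a medium differed between pre-starved and naive cultures. For genes that test was the quasi-likelihood method of edgeR, and for lists camera with its preset correlation, which called 7 lists in salt and 7 in used medium. With the estimated correlation camera called 0 in either medium, and fry called 15 and 16.

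In salt 2913 genes differed in their response. List medians of the log2 difference were -2.03 for austinol genes (-2.53 with 1 member at its bound, AN9253, which had 0 counts in naive salt cultures), -1.58 for nitrate, -2.09 for ammonium, -1.06 for glycolysis, -1.33 for gluconeogenesis and -1.48 for heat shock genes, and 0.67 for secondary metabolism regulators. Among genes the log2 difference was 1.92 for aflS, 0.85 for laeA, 1.08 for mcrA, 1.68 for hepA, 1.49 for atg1, 4.57 for AN3388 and 5.93 for AN3229. It was -2.21 for stcA, -2.70 for gltA, -3.28 for acuD and -5.88 for rodA. Levels after refeeding enter these values. The nitrate, ammonium and glycolysis lists and stcA, gltA and rodA had started higher in pre-starved than in naive cultures. The genes aflS, mcrA, atg1 and AN3229 had started lower.

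In used medium 2743 genes differed in their response. List medians were -1.79 for asperthecin, -1.07 for austinol (-2.45 with 1 member at its bound, AN8381, which had 0 counts in naive used-medium cultures), -1.76 for nitrate, -1.96 for ammonium, -0.99 for glycolysis, -0.87 for trehalose and -1.09 for heat shock genes. Levels after refeeding enter these values and those of the genes below. The asperthecin, nitrate, ammonium and glycolysis lists had started higher in pre-starved than in naive cultures, as had stcA, acvA, orsC and niaD. The gene aflS had started lower. Among genes the log2 difference was 2.40 for aflS, 1.26 for chiB and 1.40 for hepA. It was -2.17 for stcA, -2.57 for niaD, -2.10 for acvA, -4.56 for orsC and -1.37 for treB. It was 1.69 for aflR and 1.38 for aldA, but leaving out 1 culture ended the call of aflR in 6 of 8 cases and that of aldA in 7 of 8, RLE size factors ended both, and aflR stood at 3.74 and 0.37 with technical library 1 and 2 alone.

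The first pattern weighed is that 776 genes raised by the first starvation stayed higher in pre-starved than in naive cultures after refeeding. Independent lists would share 831, and 848 raised genes were lower, so the set is no larger than chance overlap gives. A share of the mycelium left in the starved state would leave about the same percent of each gene's rise, but the rise left had quartiles of 19.1% and 88.9%, a ratio of 4.66. In 166 genes the rise left was over 100%. The set holds only genes still higher, which favours large percentages, so these values alone cannot decide. In a first version of the test, on 167 strongly raised genes whether still higher or not, the percent of the starved level kept had a median of 3.11 and quartiles of 1.39 and 10.3. The percent kept includes the level without starvation, which was not taken off and can differ between genes. This ratio of 7.35 therefore cannot decide on such a share of mycelium either. Leftover mRNA without new transcription would leave no gene above its starved level, unless the pool of all mRNA shrank, since CPM is a share of it. The size of that pool was not measured. Under each of the TMM, RLE and library-total scalings 3 genes of the set were higher after refeeding than in starved cultures at a 1-sided p under 0.05 divided by the size of the set, where chance would give 0.05. They are AN0713 (log2 change 2.56, SE 0.21), AN2762 (log2 change 1.98, SE 0.14) and AN3952 (log2 change 2.08, SE 0.17), named after their values were seen. Unless the pool shrank, they argue against leftover mRNA as the cause for every gene. Of the other 773 genes 5.95% were called higher after refeeding than in starved cultures (exact 95% binomial interval 4.39 to 7.86%), where chance calls at the unadjusted p of the threshold would give 1.91%. With RLE size factors it was 6.99% (5.29 to 9.02%) against 1.89%, and with library totals 1.68% (0.898 to 2.86%) against 2.02%. The share is thus above that of chance calls with TMM and RLE and not with library totals. The set was picked through the same refed and starved cultures, so these chance shares, and the 0.05 above, hold strictly for unselected genes only. The intervals also treat genes as independent and do not cover the spread between cultures, so they are likely too narrow. For the 773 genes leftover mRNA and continued expression cannot be told apart. Both calls held for 94.1% of the set with RLE size factors but for 66.4% with library totals, so library scaling may account for part of the pattern. Lasting regulation by the earlier starvation, or by the shorter growth before it, remains open as untested.

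The second pattern weighed is the set of 326 genes induced more strongly on renewed salt starvation. Of these 21 were already higher and 76 lower after refeeding. Counting noise at low counts is argued against, since of 264 genes that meet the rule in technical library 1 alone 99.6% had a positive difference of the responses in technical library 2, which was counted on its own. A test set out before found 0.920% of the set under 1 CPM in pre-starved salt cultures, and it is not relied on because the rule itself picks genes high there. With RLE size factors 59.5% of the set kept all 3 calls and with library totals 99.4%, so library scaling stays open for the rest of the set. An effect on the response of the earlier starvation, the difference that the design names, or of the shorter growth before it stays open beside it as a hypothesis.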

How the results depend on the processing

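The comparisons of used with salt medium were chosen after seeing the data, and so were their alternatives. The other alternatives were planned. The planned change of pseudocount was not run, since the values are counts.

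No list median called by camera changed sign with RLE size factors or with library totals, and no alternative changed the sign of a named gene value that was called. Over all called genes, 0 changed sign with RLE size factors. With library totals the sign changed for 387 called genes of the first starvation, 612 of refeeding, 413 and 750 of salt in naive and pre-starved cultures, and 107 and 449 of used medium, and for none in the other comparisons. With a block for the culture letter the number of genes called was 7325 for the first starvation and 305 for fresh medium, and 48 list tests were called. The letters were not taken to pair the cultures, since the labels name no batch or day that a letter shares and the correlation of A-minus-B residuals over 28 pairs of groups was over 0.1 for 10 and under -0.1 for 12, so the block is given here as an alternative alone. The correlations have a structure, though, seen after the fact. They ran from 0.15 to 0.25 among starved, both refed and naive salt cultures, from 0.14 to 0.36 among pre-starved salt and both used-medium groups, and from -0.28 to -0.048 between these sets. A block for the letter does not take this up, and its origin was not tested. Counts stayed within 1.5-fold without the low-count filter and with limma-voom.

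With RLE size factors the genes induced more strongly on renewed salt starvation fell in number from 326 to 194. With library totals they numbered 839, those repressed more strongly 207 against 332, and those induced more strongly in used medium 580 against 236. DESeq2 called 610 genes for fresh medium and 518 for repression on renewed salt. The 32 libraries with duplicate correlation gave 581 for fresh medium and 2585 for used against salt medium in pre-starved cultures. The cause was not tested.

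Fits of only the groups of a comparison take the spread from those groups alone, with fewer cultures. They called 759 genes for fresh medium, 2497 for past starvation at used medium and 706 for used against salt medium in pre-starved cultures. They gave 109 genes induced and 237 repressed more strongly in used medium, and 1106 genes higher in both media. Cultures A and B differed by a chi-square per degree of freedom of 44.2 in grown and 53.3 in naive refed cultures. It was 272 in naive used-medium, 177 in pre-starved used-medium and 187 in pre-starved salt cultures. The spread shared by all groups thus went with fewer calls for fresh medium and more for used medium.

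Asking also for a 2-fold change, which by construction can only lower a count, left 4653 genes for the first starvation, 5089 for refeeding, 144 for fresh medium, 1503 for past starvation after refeeding, 1603 at salt and 1435 at used medium. It left 1419 and 1398 for the differences of the salt and used medium responses, and 549 and 761 for used against salt medium in naive and pre-starved cultures. With that change in all 3 comparisons, renewed salt induced 77 and repressed 142, and used medium 48 and 167. Shared between media were 538 higher and 454 lower genes, and left after refeeding 294 and 310. Of 336 list tests 47 were called with the preset correlation, 0 with the estimated correlation of camera (17 at an unadjusted p under 0.05) and 217 with fry.

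Leaving out 1 culture, with the lone culture of its group assumed to vary like the other groups, gave 64 to 128 genes for fresh medium, 206 to 305 induced and 220 to 311 repressed more strongly on renewed salt, and 135 to 213 induced more strongly in used medium. For used against salt medium it gave 568 to 976 in naive and 816 to 1752 in pre-starved cultures.

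For genes not called, the sign changed in places. The log2 change of aflR, with under 1 CPM in refed cultures, was -0.036 for fresh medium and 0.15 for past starvation after refeeding without naive refed A, and 0.80 and -0.68 without naive refed B. With technical library 2 alone it was 0.99 for past starvation after refeeding and -0.072 for the difference of the salt responses, against -2.38 and 3.60 with technical library 1 alone. That of nirA under the first starvation was 0.28 with library totals, and that of creA in naive used-medium cultures 0.14. The cause was not tested. Counts of aflR were few in refed cultures, 30 over both naive and 26 over both pre-starved cultures, so depth limits what can be said of it there.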

Other observations

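The comparison of used with salt medium, the test of library scaling for the alcohol genes, and the choice of genes named in this part were chosen only after the result was seen. The tests of an inducer and of neighbouring genes were set out before their results were seen.

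Used medium and salt were compared after 1 h in naive cultures. The alcohol dehydrogenase gene alcA stood at 16831 ± 10269 CPM in used medium and 2030.3 ± 807 CPM in salt (log2 change 3.05, SE 0.71, adjusted p 0.0139 by edgeR's quasi-likelihood test), with aldA (log2 change 1.27, SE 0.33, adjusted p 0.0222) and alcR (log2 change 0.92, SE 0.26, adjusted p 0.0350) higher too. All 3 penicillin genes were higher in used medium, acvA most (log2 change 5.0, SE 0.45, adjusted p 2.56e-05), as were all 3 tested terrequinone genes, tdiB for example (log2 change 8.09, SE 0.57, adjusted p 5.83e-06), and 3 of 5 orsellinic acid genes. Of the sterigmatocystin genes 5 of 17 were higher (6 adjusted over the list alone), aflR among them (log2 change 1.77, SE 0.31, adjusted p 0.00257). The proline genes prnD (log2 change -2.46, SE 0.30, adjusted p 2.53e-04) and prnB (log2 change -2.50, SE 0.44, adjusted p 0.00283) were lower. In all 1463 genes were called, 811 higher and 652 lower, and leaving out 1 culture gave 568 without naive salt A, 816 without naive salt B and 685 without naive used B. Of the called genes 55.4% were higher with TMM, 42.2% with RLE size factors and 29.1% with library totals.

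In pre-starved cultures 1706 genes were called between used medium and salt, 904 higher and 802 lower in used medium, which is 53.0% higher against 28.6% with library totals. The gene alcA was higher again (log2 change 2.87, SE 0.71, adjusted p 0.0152 by edgeR's quasi-likelihood test), and of the gluconeogenesis genes 6 of 8 were higher (8 adjusted over the list alone), acuD for example (log2 change 2.61, SE 0.41, adjusted p 9.03e-04). All 8 gluconeogenesis genes were higher in culture A than in B, by a median of 1.78-fold in used medium and 1.38-fold in salt. Leaving out 1 culture gave 995 genes without pre-starved used A and 816 without pre-starved salt B.

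Another pattern, chosen after its values were seen, is that alcA, alcR and aldA were all higher in used medium than in salt in naive cultures. Library scaling is argued against as the whole cause, since the smallest log2 change of the 3 genes over the TMM, RLE and library-total scalings was 0.76 (SE 0.27). That is alcR with library totals, where it was no longer called because its change was smaller. An inducer of the alc genes in the used medium, such as a product of the earlier growth, is a candidate explanation, and 3 of the 6 tested neighbours of alcA and alcR were called higher, a number that lies between what its presence and its absence were set to predict. Of all tested genes 8.09% were called higher in this comparison. Neighbours of alcR may also rise with it whatever raises it, so their number cannot decide. Whether the used medium held such an inducer therefore stays open. No compound was measured in the used medium.

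Cultures A and B of a group differed in several clusters, that of the benzaldehyde derivative among them. In pre-starved used-medium cultures the genes of that cluster differed by a median of 19.0-fold, with 11 of 11 higher in A. Its genes differed too in pre-starved salt (3.58-fold) and naive used-medium cultures (2.23-fold), again with all 11 higher in A. All 11 were higher in B in starved (8.85-fold) and pre-starved refed cultures (4.61-fold). In grown, naive refed and naive salt cultures the median was 1.27, 1.24 and 1.36-fold, with members going both ways. All orsellinic acid genes were higher in B in starved (4.05-fold) and pre-starved refed cultures (4.64-fold), as were all terrequinone genes (3.02 and 3.03-fold). All emericellamide genes were higher in B in pre-starved used-medium (2.16-fold) and salt cultures (2.00-fold), and all genes of the alcohol list were higher in A in pre-starved salt cultures (2.16-fold).

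A hypothesis tested was that renewed starvation acts on runs of neighbouring genes. Among the 304 of 326 genes induced more strongly in salt that have a place in the gene order, 27 pairs were adjacent. Draws of as many genes from those raised by salt in pre-starved cultures gave a median of 12 (1-sided permutation p 7e-05, 100000 permutations). In used medium 13 pairs were adjacent against a median of 6 (1-sided permutation p 0.009). Runs included AN7535, AN7536 and AN7537 in both media, and aflS with aflR in used medium. Both sets thus held more adjacent pairs than random draws. The draws take genes singly, and no other gene set was put to this test. Neighbours that move together in any comparison therefore cannot be told from an effect of renewed starvation on runs. Reads shared by overlapping genes were not tested either as a source of such pairs.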
